A study of Nannochloropsis oceanica with 36 samples.

How the data were processed

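The data are mRNA-seq libraries of Nannochloropsis oceanica IMET1 grown in modified f/2 medium, an enriched seawater medium, with 1 g/l NaNO3 under continuous light of about 50 µmol photons per square metre and second at 25 °C with 1.5% CO2 in air, per the labels' protocols. Washed mid-logarithmic cells were moved to N-replete or N-deprived medium and sampled at 3, 4, 6, 12, 24 and 48 h, with 3 biological replicate cultures in each medium. Total RNA was extracted, poly(A) RNA was purified on oligo(dT) beads and broken to 200 to 300 bp, cDNA was primed with random hexamers, and strand-nonspecific libraries were sequenced as 90 bp read pairs, per the labels' protocols. A label field gives the molecule as nuclear RNA, while the protocol describes total RNA of whole cells. Selection of poly(A) RNA leaves organelle transcripts without poly(A) tails underrepresented, and without strand information reads of overlapping genes on opposite strands cannot be told apart.

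The deposited values are FPKM per gene model, which the authors made with TopHat2 2.0.4 and Cufflinks 2.0.2, per the submitters' processing notes, which name no role or setting. The genome build and annotation were not given in the sources used here. Each of 36 tables held 1 library, and a table of the whole series held the same values, with 0 differing. FPKM divides by gene length and by the fragments of the library, so a change is a change in share: a fall of abundant transcripts raises all others. Fragments shared between near-identical genes can be split between them by Cufflinks, which bears on neighbouring or duplicated genes. Exact zeros can be failed estimates as well as absence.

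There were 9756 gene models on 284 sequences, with a median locus length of 2136 bp including introns. The files give each locus as sequence, start and end, with a start counted from 0 that was raised by 1 for the positions printed, and no exons or strand. The files pair 1 identifier with a gene symbol, and 0 of 9756 identifiers matched the reference table used (160 genes, assembly ASM5162214v2). That table holds only organelle genes, so identifiers were not checked against an annotation of nuclear genes. For that reason tests of the 36 gene lists fixed before the data were examined (nitrogen assimilation, photosynthesis, lipid synthesis and others) could not be run, with their alternatives, and no theme is assigned to unnamed genes.

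Groups were taken from the library titles. Values were transformed to log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, 9647 of 9756. A linear model with a mean for each of 12 groups over all 36 libraries was fitted with limma 3.58.1 in R 4.3.3, with moderated variances and a trended prior, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. Comparisons were N-deprived with N-replete medium at each time, the mean of these 6 effects, their difference between times (F test), the mean of the last 3 less that of the first 3, and time within each medium (F tests). Calls shared between consecutive times were set beside the number independent lists would share. All tests are two-sided or F tests. Fold changes are on the log2(FPKM + 1) scale and understate the change of genes near or below 1 FPKM. These comparisons, the gene filter, the rule for named genes and all alternatives but 1 were fixed before the data were examined. Steps between consecutive times, counts of genes changed at all 6 times or in opposite directions, and the analysis of neighbouring genes were chosen afterwards.

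Per the labels' protocols, 3 cultures were set up in each medium and aliquots taken at each time, without saying whether a replicate number follows 1 culture. The summed FPKM of replicate 3 was the highest of its group at 6 of 6 times in N-replete medium and the lowest at 6 of 6 times in N-deprived medium, so a number carried some factor over time. Beyond such shifts of whole libraries, deviations of single genes from their group mean carried over little. Their correlation across genes between times averaged 0.005 for the same number in N-replete and -0.032 in N-deprived medium. A correlation across genes leaves out a shift of all genes alike, so it does not bear on the factor seen in the sums. Libraries entered the model as independent, and where they are not the p-values of effects averaged over time are too small. Culture as a random effect (estimated correlation 0.122) was an alternative. An exact rank comparison of 3 with 3 libraries cannot give a two-sided p under 0.10. Single-gene calls therefore rest on the linear model, which pools each gene's variance over all 12 groups and moderates it with that of other genes. Groups of 3 are too small for a test of single outlying libraries. Replicates were distinct: at most 0.01% of values above 0 were equal between a pair of replicates.

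Named genes were chosen by rule. At each time the rule took up to 2 risen and 2 fallen identifiers with the largest change among called genes whose 3 libraries in either medium did not overlap. It added the 2 with the smallest interaction p, the 2 with the highest mean FPKM in N-replete medium, and the diacylglycerol acyltransferase named in the files. That gave 16 genes.

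Absolute depth is unknown. Relative depth was estimated from 101 low genes, in which 96.6% of 1786 values came out within 0.1 of a whole number of fragments, against 37.0% after random rescaling. The estimate starts from minima scaled by locus length and its settings were chosen on these data, so it depends on that start, and it was not used in any test. The highest value, 2.623, was that of 1 library (N-replete 24 h replicate 1); the other 35 lay between 0.704 and 1.586. Deeper libraries measure low genes with less counting error, and no interval for counting error can be given without the totals.

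The model was tested on simulated data for 3 h with 9647 genes and 50 genes at each fold: 42% of genes changed 1.25-fold, 86% at 1.5-fold, 90% at 2-fold and 100% at 4-fold were called, and 3.05% of calls were unchanged genes. The interaction test called 10%, 64%, 84% and 100%, with 5.15% of calls unchanged genes. In the simulation all other genes and times had no effect of medium, and noise was normal and independent between genes and libraries. In the data 40% of genes were called at 3 h and whole libraries shifted, so these shares need not hold for them. The depth estimate was tested from a start close to the simulated depths, a lenient test.

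Alternatives were a pseudocount of 0.1, no filter, median-ratio centring of each library, quantile normalization, a model of 1 time at a time, replicate number as a block, culture as a random effect, culture means, a 2-fold threshold, an untrended prior and leaving out each library. Leaving out the 12 h libraries was added after the data were examined. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 was used for tables, permutations and plots.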

Results

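Messenger RNA was sequenced from Nannochloropsis oceanica IMET1, a unicellular oleaginous marine alga (a eustigmatophyte), after transfer to nitrogen-replete (N-replete) or nitrogen-deprived (N-deprived) medium. Mid-logarithmic cells were washed and moved to either medium under continuous light, and both media were sampled at 3, 4, 6, 12, 24 and 48 h. Each of the 12 groups had 3 biological replicates, 36 libraries in all, with an FPKM value (sequenced fragments scaled to transcript length and to the mapped fragments of the library) for each of 9756 gene models. The sum of FPKM lay between 475304 and 629498 per library, and between 23 and 69 gene models were listed at 0. Total fragment numbers were not given. A relative depth was fitted so that low FPKM values became whole numbers of fragments, which 96.6% of 1786 values from 101 low genes then were within 0.1, and it ran from 0.704 in N-deprived 6 h replicate 1 to 2.623 in N-replete 24 h replicate 1. Pearson's r of log2(FPKM + 1) across genes between replicates of a group was 0.9849 to 0.9962, across genes that are not independent replicates. The files pair 1 gene model with a gene name and leave the rest as identifiers, so most genes are given by identifier and position, with 1-based positions on the scaffolds of a genome build not given in the sources used here.

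More genes were changed by nitrogen deprivation from 12 h on than at 3, 4 and 6 h. In the comparison of N-deprived with N-replete medium, 113 genes rose and 227 fell at least 2-fold at 3 h, 124 rose and 165 fell at 4 h, and 124 rose and 135 fell at 6 h. By 12 h 398 had risen and 373 had fallen, by 24 h 676 had risen and 461 had fallen, and by 48 h 1028 had risen and 896 had fallen at least 2-fold. Of 9647 genes tested with limma, 40% passed a Benjamini-Hochberg adjusted p of 0.05 at 3 h. At 4 and 6 h 32.5% and 34.6% passed. At 12, 24 and 48 h 62.5%, 67.8% and 75.9% passed. Most calls were therefore of changes under 2-fold. These tests share a variance per gene over all times. With only the libraries of each time in the model, 4237, 3357 and 2869 genes passed at 3, 4 and 6 h. At 12, 24 and 48 h 4784, 6345 and 7606 passed. The 12 h number thus fell from 6033 and lay nearer that of 3 h. Other splits of the 12 h libraries called up to 1428 genes, against at most 4 at other times. The number of calls at 12 h is therefore less certain. FPKM is a share of each library, and the median log2 change of all genes was above 0 at every time, from 0.04 at 6 h to 0.16 at 48 h. After each library was centred on its median log2 ratio, that median moved by -0.16 at 24 h and -0.15 at 48 h, and the genes at least 2-fold changed became 322 up and 464 down at 12 h, 482 up and 640 down at 24 h, and 718 up and 1133 down at 48 h. With quantile normalization they were 339 up and 357 down at 12 h, 600 up and 544 down at 24 h and 914 up and 1085 down at 48 h. The numbers at 6 h were close, and a pseudocount of 0.1 gave 171 up and 158 down.

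**Figure D1:**
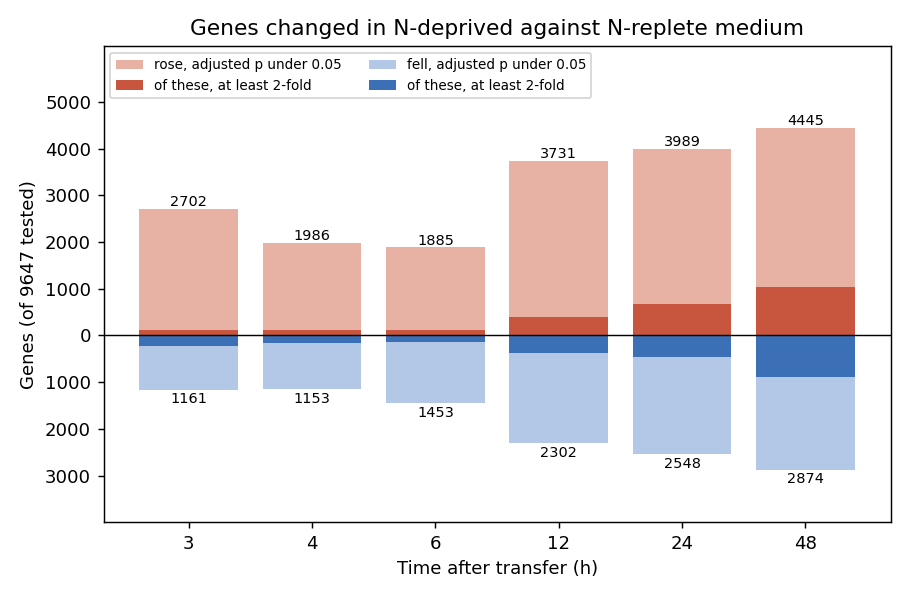
Genes higher (above 0) and lower (below 0) in N-deprived than in N-replete medium at each time in hours, with those passing an adjusted p of 0.05 in pale bars and those of them changed at least 2-fold in dark bars. The dark bars rose from 113 up and 227 down at 3 h to 1028 up and 896 down at 48 h with FPKM as deposited; with libraries centred on their median ratio the 48 h numbers were 718 up and 1133 down, and with quantile normalization 914 up and 1085 down.

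The gene named in the files, isotig00738.DGAT1A, carries the symbol of a type 1 diacylglycerol acyltransferase, an enzyme class that makes triacylglycerol from diacylglycerol in the last step of storage lipid synthesis. It was higher in N-deprived medium at all 6 times. Its level at 3 h was 50.4 ± 3.39 FPKM (SD, n = 3) in N-deprived and 30.3 ± 0.635 FPKM (SD, n = 3) in N-replete medium, a log2 difference of 0.71 (SE 0.069; limma, Benjamini-Hochberg adjusted p = 5.07e-10). At 24 h the levels were 55.9 ± 1.15 and 21.8 ± 1.93 FPKM (SD, n = 3 each), a log2 difference of 1.32 (SE 0.069; limma, adjusted p = 6.60e-17), and at 48 h 63.6 ± 5.90 and 27.6 ± 1.81 FPKM, a log2 difference of 1.17 (SE 0.069; limma, adjusted p = 8.45e-16). The mean over the 6 times was 0.93 (SE 0.028; limma, adjusted p = 1.21e-23). Its model lies on its own sequence, isotig00738, at positions 1 to 2030.

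After 3 h in N-deprived medium the falls were deeper than the rises: 8 genes had fallen at least 8-fold and 0 had risen that far. Transcripts of scaffold00009.g888 (scaffold00009, 1534818 to 1539216) stood at 6.67 ± 1.59 FPKM against 322 ± 25.2 FPKM in N-replete medium (SD, n = 3 each), 42.5-fold lower on the log2(FPKM + 1) scale. Those of scaffold00271.g7988 (scaffold00271, 263203 to 267456) stood at 11.5 ± 3.17 against 435 ± 4.62 FPKM (SD, n = 3 each), 35.5-fold lower. Rises were led by scaffold00185.g5781 (scaffold00185, 103660 to 108586), with 51.5 ± 3.12 against 9.69 ± 0.639 FPKM, and by scaffold00354.g10029 (scaffold00354, 152757 to 157811), with 192 ± 1.88 against 42.6 ± 1.34 FPKM (SD, n = 3 each). The log2 changes were -5.41 (SE 0.238), -5.15 (SE 0.258), 2.30 (SE 0.106) and 2.15 (SE 0.080), with limma's Benjamini-Hochberg adjusted p of 1.14e-17, 1.84e-16, 2.79e-17 and 2.45e-19. In all, 2702 genes rose and 1161 fell, of which 69.9% were rises; with median-ratio centring 57.5% of calls were rises, and with quantile normalization 56.5%.

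At 4 h the genes that led at 3 h still stood apart. Transcripts of scaffold00185.g5781 were 8.17-fold higher in N-deprived medium, at 101 ± 7.00 against 11.4 ± 0.171 FPKM (SD, n = 3 each), and those of scaffold00354.g10029 were 5.81-fold higher. The deepest falls among genes whose libraries did not overlap were of a pair of neighbours on scaffold00009, scaffold00009.g887 (1532269 to 1534723) and scaffold00009.g888, 21.9-fold and 15.01-fold lower. Log2 changes were 3.03 (SE 0.106), 2.54 (SE 0.080), -4.45 (SE 0.233) and -3.91 (SE 0.238), with limma's Benjamini-Hochberg adjusted p of 3.24e-20, 3.40e-21, 7.85e-16 and 1.97e-14. In all, 1986 genes rose and 1153 fell.

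By 6 h the largest rises were of scaffold00354.g10029, 7.56-fold higher in N-deprived medium, and scaffold00267.g7871 (scaffold00267, 1047880 to 1049737), 5.34-fold higher at 30.1 ± 1.64 against 4.93 ± 1.37 FPKM (SD, n = 3 each). The largest falls were of scaffold00259.g7283 (scaffold00259, 287340 to 288705), 9.11-fold lower at 7.83 ± 2.32 against 78.1 ± 9.96 FPKM (SD, n = 3 each), and of scaffold00009.g887, 8.22-fold lower. Log2 changes were 2.92 (SE 0.080), 2.42 (SE 0.153), -3.19 (SE 0.210) and -3.04 (SE 0.233), with limma's Benjamini-Hochberg adjusted p of 1.69e-22, 7.76e-14, 1.98e-13 and 4.90e-12. In all, 1885 genes rose and 1453 fell.

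At 12 h the largest falls were no longer those of 3 h. Transcripts of scaffold00185.g5950 (scaffold00185, 595276 to 598245) stood at 33.6 ± 5.38 FPKM in N-deprived against 517 ± 27.99 FPKM in N-replete medium (SD, n = 3 each), 15.1-fold lower. Transcripts of scaffold00096.g3545 (scaffold00096, 272167 to 274734) were 16.7-fold lower, at 4.02 ± 0.670 against 82.8 ± 11.4 FPKM. Rises were led by scaffold00354.g10029, 11.6-fold higher, and scaffold00185.g5781, 9.90-fold higher at 276 ± 34.4 against 27.1 ± 4.16 FPKM (SD, n = 3 each). Log2 changes were -3.92 (SE 0.096), -4.06 (SE 0.130), 3.53 (SE 0.080) and 3.31 (SE 0.106), with limma's Benjamini-Hochberg adjusted p of 2.97e-24, 1.27e-21, 5.92e-25 and 1.14e-21. Of 6033 genes called, 3731 rose and 2302 fell. Rises were 61.8% of calls, against 52.1% with median-ratio centring and 51.1% with quantile normalization. With only the 12 h libraries in the model, 4784 genes were called. The 6 libraries of 12 h stood apart from the other 30 in both media: they lay at 96.9 to 102.1 on the first principal component (53.1% of the variance), the others at -44.4 to 5.0.

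**Figure D2:**
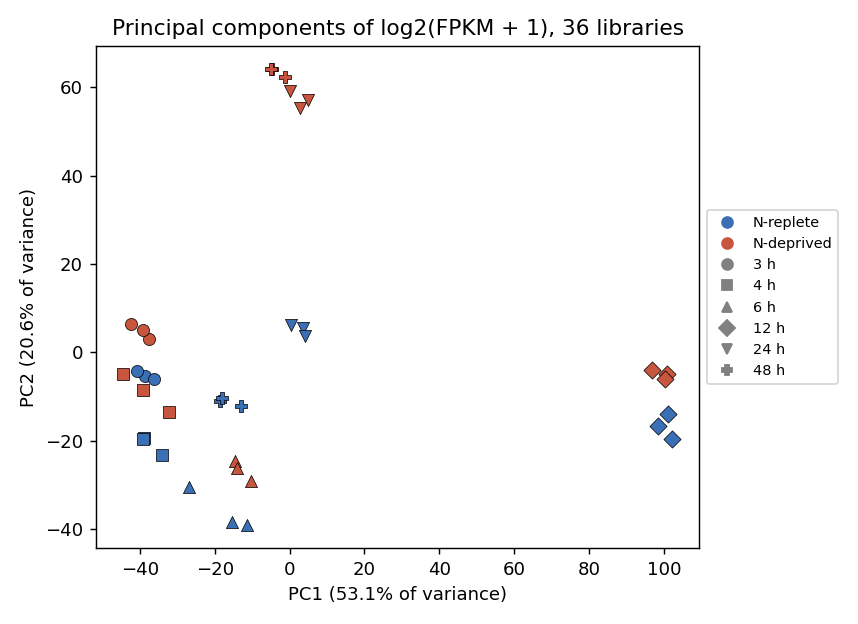
First 2 principal components of log2(FPKM + 1) over 36 libraries, in arbitrary units, with the medium as colour and the time as marker. The 6 libraries of 12 h lie at 96.9 to 102.1 on the first component (53.1% of the variance) and the 6 N-deprived libraries of 24 and 48 h at 55.2 to 64.2 on the second (20.6%), where the other libraries reach at most 6.5.

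At 24 h the most abundant transcript of the N-replete libraries, scaffold00069.g2383 (scaffold00069, 445093 to 446789), stood at 323 ± 8.005 FPKM in N-deprived against 10008 ± 297 FPKM in N-replete medium (SD, n = 3 each), 30.9-fold lower. On the same scaffold, scaffold00069.g2456 (642714 to 644318) was 23.2-fold lower, at 0.480 ± 0.367 against 35.2 ± 15.6 FPKM (SD, n = 3 each). Its N-deprived level lay below 1 FPKM, where the added 1 FPKM holds down the fold. Transcripts of scaffold00214.g6293 (scaffold00214, 718944 to 720038) were 32.6-fold higher, at 97.4 ± 6.00 against 2.03 ± 0.369 FPKM, and those of scaffold00185.g5904 (scaffold00185, 458230 to 459184) 30.7-fold higher, at 175 ± 12.3 against 4.72 ± 0.252 FPKM (SD, n = 3 each). Log2 changes were -4.95 (SE 0.111), -4.54 (SE 0.25), 5.03 (SE 0.148) and 4.94 (SE 0.125), with limma's Benjamini-Hochberg adjusted p of 8.71e-26, 2.66e-16, 4.72e-23 and 1.69e-24. Of 6537 genes called, 3989 rose and 2548 fell, 61.0% rises. With median-ratio centring 45.6% of calls were rises and with quantile normalization 48.7%, so which direction held more genes depended on the scaling.

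At 48 h scaffold00069.g2383 had fallen further, to 73.5 ± 6.75 FPKM against 11385 ± 743 FPKM in N-replete medium (SD, n = 3 each), 153-fold lower. It made up 0.014% of the summed FPKM in N-deprived and 2.00% in N-replete medium at 48 h. Transcripts of scaffold00185.g5950 were 40.5-fold lower, at 28.1 ± 1.61 against 1180 ± 34.5 FPKM (SD, n = 3 each). On scaffold00214, scaffold00214.g6293 reached 243 ± 14.6 against 0.872 ± 0.469 FPKM (SD, n = 3 each), 133-fold higher. Its neighbour scaffold00214.g6292 (715988 to 716939) stood at 51.6 ± 4.33 FPKM (SD, n = 3), 42.9-fold higher, against N-replete libraries at 0, 0.138 and 0.609 FPKM, levels at which the added 1 FPKM holds down the fold. Log2 changes were -7.26 (SE 0.111), -5.34 (SE 0.096), 7.05 (SE 0.148) and 5.42 (SE 0.214), with limma's Benjamini-Hochberg adjusted p of 3.70e-30, 2.83e-28, 8.02e-27 and 3.88e-20. Libraries of the media did not overlap for 79.4% of genes tested, where chance gives 10% for a single gene at 3 against 3. This was counted without centring. The median FPKM of the libraries did not overlap either, at 27.61 or less in N-replete and 28.23 or more in N-deprived medium. The summed FPKM separated the media the other way, as at every other time, at 557295 or more in N-replete and 547491 or less in N-deprived medium. A shift of whole libraries can therefore add to this share. Of 7319 genes called, 4445 rose and 2874 fell, 60.7% rises against 50.0% with median-ratio centring and 52.9% with quantile normalization.

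**Figure D3:**
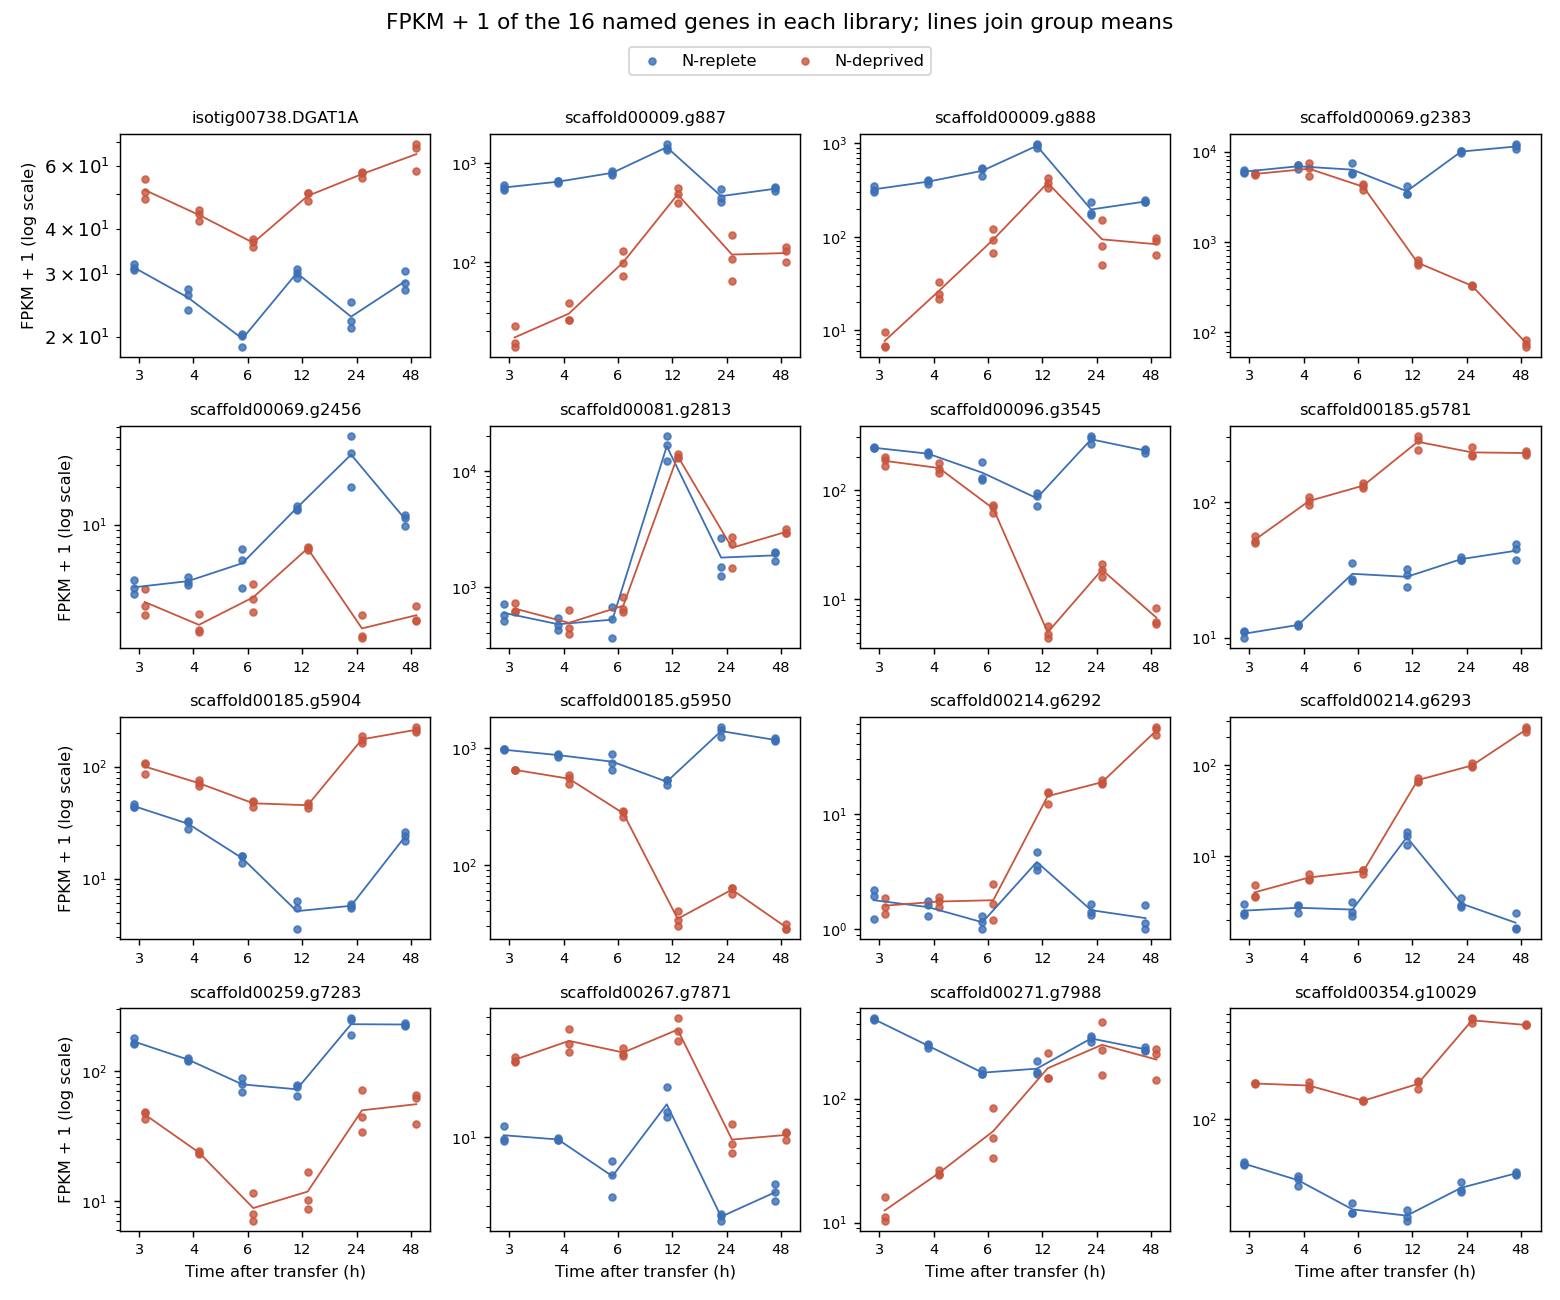
FPKM + 1 on log axes against time in hours for the 16 named genes, with 1 point per library (n = 3 per group) and lines through the group means, N-replete in blue and N-deprived in red. The N-deprived line of scaffold00069.g2383 falls to 73.5 FPKM at 48 h while the N-replete line reaches 11385 FPKM, and isotig00738.DGAT1A is higher in N-deprived medium at all 6 times.

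Averaged over the 6 times, 226 genes were at least 2-fold higher and 194 at least 2-fold lower in N-deprived medium. The mean log2 effect was 3.27 (SE 0.033; limma, Benjamini-Hochberg adjusted p = 1.29e-35) for scaffold00354.g10029, 2.64 (SE 0.043; adjusted p = 2.63e-30) for scaffold00185.g5781 and -3.07 (SE 0.095; adjusted p = 2.22e-23) for scaffold00009.g887, and these 3 genes were called in 1 direction at all 6 times. A set of 42 genes rose and 10 fell at least 2-fold at every time; with median-ratio centring the numbers were 36 and 15. In total 7358 genes had a mean effect with adjusted p under 0.05 in limma, 4646 up and 2712 down, 63.1% rises against 48.8% with median-ratio centring and 49.2% with quantile normalization. With culture as a random effect, as if each replicate number followed 1 culture over time, 6737 genes were called.

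The response to nitrogen deprivation differed between times for most genes by an F test, which sets no limit on the size of the difference. Some genes were lowest against N-replete medium at 3 h: scaffold00271.g7988 went from -5.15 on the log2 scale at 3 h to -0.02 (SE 0.258; limma, Benjamini-Hochberg adjusted p = 0.963) at 12 h and -0.32 (SE 0.258; adjusted p = 0.266) at 48 h, and scaffold00009.g888 from -5.41 to -1.54 (SE 0.238; adjusted p = 9.13e-07). Others changed late: scaffold00069.g2383 differed by -0.08 (SE 0.111; limma, adjusted p = 0.591) at 3 h and -7.26 at 48 h. The F test of the interaction of medium and time called 8070 of 9647 genes (83.7%), with the smallest p for scaffold00069.g2383 (limma, adjusted p = 2.07e-26) and scaffold00185.g5950 (adjusted p = 5.01e-24). The mean effect at 12, 24 and 48 h less that at 3, 4 and 6 h passed for 6199 genes, 3613 with a more positive and 2586 with a more negative late effect. Positive differences were 58.3% of these calls, against 46.1% with median-ratio centring and 51.5% with quantile normalization. Most of these differences were under 2-fold: 221 genes were at least 2-fold more positive and 213 at least 2-fold more negative late.

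Consecutive times shared many of their calls, and the effects at 3 and 48 h were only weakly correlated. Between 3 and 4 h 1687 genes rose and 882 fell at both times, where independent lists would share 556 and 139; between 24 and 48 h 3375 rose and 2052 fell at both, where 1838 and 759 would be shared. In the steps between, 1178 rose and 767 fell at both 4 and 6 h, 1454 and 1107 at both 6 and 12 h, and 2306 and 1281 at both 12 and 24 h, where 388 and 174, 729 and 347, and 1543 and 608 would be shared. Opposite directions were called for 901 genes at 12 and 24 h. They were called for 5 at 3 and 4 h, 47 at 4 and 6 h, 130 at 6 and 12 h and 182 at 24 and 48 h. Scaling moved these splits: with median-ratio centring the shared rises and falls were 1464 and 1189 for 3 and 4 h, 1742 and 1881 for 12 and 24 h, and 2604 and 2904 for 24 and 48 h. Pearson's r of the log2 effects across genes, which are not independent replicates, was 0.88 for 3 and 4 h, 0.86 for 24 and 48 h and 0.27 for 3 and 48 h. Of the 227 genes at least 2-fold lower at 3 h, 32 were so at 48 h and 49 were called higher. Of the 113 at least 2-fold higher at 3 h, 73 were so at 48 h and 3 were called lower. Among all 9647 genes tested, 4445 were called higher and 2874 lower at 48 h, 1028 and 896 of them at least 2-fold. A call in the other direction at 48 h was thus rarer in both sets than among all genes. With median-ratio centring 57 genes rose and 49 fell at least 2-fold at both 3 and 48 h. No library is shared between times, but all times share 1 variance per gene, and the same cultures may have been sampled at each time. Calls at 2 times are therefore not independent, which the numbers for independent lists leave out.

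**Figure D4:**
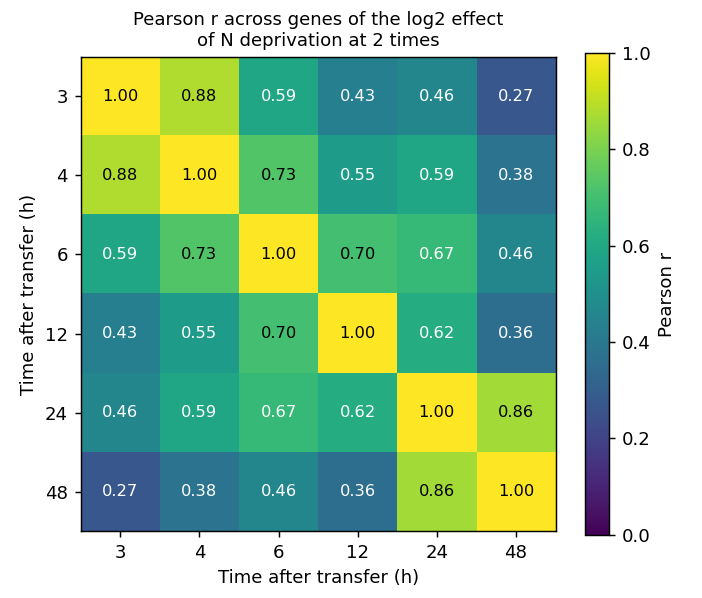
Pearson's r across 9647 genes between the log2 effects of N deprivation at each pair of times in hours, as colour and number. It is 0.88 for 3 and 4 h, 0.86 for 24 and 48 h and 0.27 for 3 and 48 h.

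Transcript levels differed between times after transfer in both media, N-replete medium included. For the 12 h libraries, handling and a state of the cultures cannot be told apart. The gene scaffold00081.g2813 (scaffold00081, 57816 to 59427), number 2 by mean FPKM over all N-replete libraries and number 44 without those of 12 h, went from 523 ± 157 FPKM at 6 h to 16355 ± 4032 FPKM at 12 h in N-replete medium and from 690 ± 114 to 13446 ± 577 FPKM in N-deprived medium (SD, n = 3 each). It then stood at 1877 ± 172 and 2994 ± 122 FPKM at 48 h, where the media differed by 0.68 on the log2 scale (SE 0.234; limma, Benjamini-Hochberg adjusted p = 0.0102). It passed at no other time with FPKM as deposited, and at 6 and 24 h with quantile normalization (log2 0.77 and 1.37). The F test over time called 9578 genes within N-replete and 9600 within N-deprived medium (limma, adjusted p under 0.05). With times reshuffled between libraries of a medium, up to 8422 and 7230 genes still passed. From 6 to 12 h 1041 genes rose and 3071 fell at least 2-fold in N-replete medium, and 1021 and 2546 in N-deprived medium; these steps were compared after the data had been examined. With median-ratio centring the same step gave 1674 and 651 in N-replete and 1653 and 611 in N-deprived medium, so the direction of most of this change depended on the scaling.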

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

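The tests of the 12 h libraries and of the excess of rises and the regrouping of whole cultures were chosen only after the result was seen; the regrouping of single libraries was planned.

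The effect of nitrogen deprivation differed between times for 8070 genes by the F test of the interaction in limma, and 6199 genes differed between the mean effect at 12, 24 and 48 h and that at 3, 4 and 6 h. Replicate numbers carried a factor over time, so whole cultures (medium and number) were regrouped, which makes 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 8070 and 0 for the interaction, 6199 and 0 for late less early, and 7358 and 0 for the mean effect. Regrouping single libraries 100 times, which treats them as independent, gave at most 1026, 2720 and 1472 genes in the others. For time within a medium, 1 of 100 regroupings, the real one, gave as many genes. The counts were 9578 against at most 8422 in N-replete and 9600 against at most 7230 in N-deprived medium. The other medium kept its real groups in the shared variance, and regrouped times still called up to these numbers. So the regroupings argue against a random order of times, but do not bear out the number of genes called. With times reshuffled within each replicate number the highest of the others were 7997 and 8682. At single times the 6 libraries make 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 3863 and 0 at 3 h and 3139 and 1 at 4 h. They were 3338 and 4 at 6 h and 6033 and 1428 at 12 h. At 24 h they were 6537 and 2, and at 48 h 7319 and 0. Each time 1 split, the real one, reached the real count. The 1428 genes called in another split leave the number of calls at 12 h less certain than at the other times.

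Among the named genes, 15 had an effect that differed between times by the interaction test. Most of these genes were chosen for large effects in these same data, and 83.7% of all genes tested passed. In log2 units the late less early effect was -4.68 for scaffold00069.g2383 (-4.677), -3.73 for scaffold00096.g3545 (-3.727), -3.69 for scaffold00185.g5950 (-3.688), -1.90 for scaffold00069.g2456 and -0.58 for scaffold00267.g7871 (-0.579). It was 3.66 for scaffold00214.g6293 (3.664), 3.47 for scaffold00214.g6292 (3.466), 3.20 for scaffold00271.g7988 (3.204), 2.58 for scaffold00009.g888 (2.578), 2.42 for scaffold00185.g5904 (2.424), 2.23 for scaffold00009.g887 (2.234) and 1.47 for scaffold00354.g10029 (1.466), the 3 falling genes among these meaning a fall that eased. It was 0.28 for isotig00738.DGAT1A (0.279), whose rise was larger late. For scaffold00185.g5781 it was 0.27 (0.274), but 0.18 after median-ratio centring and 0.006 without the 12 h libraries, neither past the threshold in limma, so a late change is not established. For scaffold00259.g7283 it was 0.14 (0.141) with a limma adjusted p of 0.487, and its difference between times rests on the F test (adjusted p = 0.00283).

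The 6 libraries of 12 h stood apart from the other 30 in both media, with a median FPKM of 17.6 to 20.7 against 24.3 to 30.9 and a share of the 10 highest genes of 13.4% to 14.8% against 4.20% to 7.01%. That a few abundant genes lowered all others alike is argued against as the whole cause: after median-ratio centring 2325 genes still changed at least 2-fold from 6 to 12 h in N-replete medium against 501 from 4 to 6 h. Loss of long transcripts is argued against by Spearman's rho across genes between locus length and that change, 0.002 in N-replete and 0.061 in N-deprived medium. Handling confined to these libraries and a state of the cultures at 12 h cannot be told apart, since all libraries of 12 h share both: the change was alike in the media (Pearson's r 0.94 across genes), and its r with the difference of 24 h from 48 h was 0.51 in N-replete and 0.18 in N-deprived medium.

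With FPKM as deposited more calls were rises than falls at each time. Among genes changed at least 2-fold, however, more fell than rose at 3 and 4 h. At 6 h 124 of these rose and 135 fell, but 171 and 158 with a pseudocount of 0.1. With median-ratio centring calls were 3659 up and 3659 down at 48 h and 3073 up and 3663 down at 24 h. In FPKM a loss of abundant transcripts may raise the share of all others, and the tables leave this open, because the predicted size depends on which abundant genes are taken. The log2 shift predicted at 48 h was 0.194 from the 100 genes highest in N-replete medium, -0.064 from the 100 highest in N-deprived medium and 0.13 from the 100 highest in the mean of both, against a measured median of 0.159. At 24 h these were 0.25, 0.013 and 0.17 against 0.115, and at 3 h 0.08, 0.026 and 0.062 against 0.1. No measure of RNA per cell was used here.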

How the results depend on the processing

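Leaving out the 12 h libraries was chosen only after the data were seen; all other alternatives were planned. For the planned comparisons the count of calls moved by over 1.5 times under 1 setting, a 2-fold threshold added to the adjusted p, which gave 340 genes at 3 h, 289 at 4 h, 259 at 6 h, 771 at 12 h, 1137 at 24 h, 1924 at 48 h and 420 for the mean effect; this setting asks for more by construction. No call of a named gene changed direction. Leaving out 1 library gave 3258 to 3706 genes at 3 h, 2653 to 2816 at 4 h, 2689 to 3316 at 6 h, 5534 to 5895 at 12 h, 6102 to 6287 at 24 h and 6966 to 7141 at 48 h. The ranges were 7259 to 7419 for the mean effect, 7872 to 8150 for the interaction, 6065 to 6381 for late less early, and 9561 to 9583 and 9589 to 9609 for time within N-replete and N-deprived medium. Shared calls ranged from 2260 to 2454, 1714 to 1904, 2154 to 2633, 3367 to 3638 and 5146 to 5357 in order of time. With the model of 1 time the counts were 4237, 3357, 2869, 4784, 6345 and 7606; without the 12 h libraries 4142, 3462 and 3675 at 3, 4 and 6 h and 6717 and 7489 at 24 and 48 h. At least 2-fold, single libraries turned which direction held more genes at 6 h, with 125 up and 107 down without N-replete replicate 3 and 124 and 121 without N-deprived replicate 1. They did so at 12 h, with 361 and 365 without N-replete replicate 1, 398 and 436 without N-replete replicate 2, 394 and 402 without N-deprived replicate 1, and 379 and 407 without N-deprived replicate 2. At 4 h 63.3% of calls were rises, 53.7% with median-ratio centring and 54% with quantile normalization, and at 6 h 56.5%, 53% and 50.4%. With quantile normalization 3661 genes were called at 3 h and 3709 at 6 h. Culture means gave 6736 genes for the mean effect. Genes at least 2-fold changed from 6 to 12 h in N-replete medium, a comparison not planned, went from 4112 to 2325 with median-ratio centring and 2464 with quantile normalization. From 12 to 24 h in N-replete medium they went from 3192 to 1835 and 1902. In N-deprived medium median-ratio centring took 3567 to 2264 from 6 to 12 h and 4415 to 2390 from 12 to 24 h. From 3 to 4 h in N-replete medium 111 genes became 186 with a pseudocount of 0.1 and 54 with quantile normalization.

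Over the 6 times together, correlations across genes did not pair the libraries by replicate number. Those of same-numbered deviations ran from -0.27 to 0.41, 4 of 18 pairs were over 0.1, and 5 of 18 N-deprived libraries correlated best with their own number. The pairs over 0.1 were all at 4 h (0.41 and 0.3) and 6 h (0.29 and 0.15). A factor shared by number is therefore not ruled out at these times. A replicate block gave 3788, 3068, 3266, 5961, 6492 and 7293 genes at the 6 times, 7321 for the mean effect, 7995 for the interaction and 6151 for late less early, and changed no call of a named gene.

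Of single genes (log2 changes), quantile normalization ended the calls of scaffold00096.g3545 (-0.26) and scaffold00185.g5950 (-0.12) at 3 h and of scaffold00069.g2383 (-0.32) and scaffold00214.g6292 (0.42) at 6 h, and scaffold00081.g2813 passed at 6 h (0.77) and 24 h (1.37). With the model of 1 time, scaffold00214.g6292 at 6 h no longer passed (0.58) and scaffold00271.g7988 at 48 h did (-0.32). Single libraries decided some calls. At 6 h scaffold00069.g2456 no longer passed without N-replete replicate 1 (-0.66) or N-deprived replicate 2 (-0.70), and scaffold00214.g6292 without N-replete replicate 2 (0.48) or 3 (0.59) or N-deprived replicate 2 (0.60) or 3 (0.31). The same held for scaffold00096.g3545 without N-deprived replicate 2 at 3 h (-0.33) and without N-deprived replicate 1 at 4 h (-0.37). Calls arose for scaffold00081.g2813 without N-replete replicate 1 at 6 h (0.64) and without N-replete replicate 3 (0.63) or N-deprived replicate 3 (0.57) at 24 h, and for scaffold00271.g7988 without N-deprived replicate 2 at 24 h (-0.65). The cause was not tested. Low genes are limited by depth, which is known only in relative terms.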

Other observations

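The counts and the tests of neighbouring genes in this part were chosen only after the result was seen; the calls at single times that they count come from planned comparisons.

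Genes called in opposite directions at 3 and 48 h were fewer than independent lists would share. At 3 h 549 genes were higher in N-deprived medium and at 48 h lower, where 805 would be shared, and 420 were lower and then higher, where 535 would be (limma, adjusted p under 0.05 at both times). In the same direction, 1620 rose and 508 fell at both times, where 1245 and 346 would be shared. Both times share 1 variance per gene, so their calls are not independent. At least 2-fold at both times, 11 genes went from lower to higher and 0 from higher to lower, although by adjusted p alone 549 did the latter. The sum of both directions was 969 with FPKM as deposited, 1024 after median-ratio centring and 1050 after quantile normalization. In contrast, 500 genes were called at no time, and 2540 were at least 2-fold changed at 1 or more times.

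From 12 to 24 h, after the step to 12 h, many genes changed again. Those at least 2-fold changed were 2139 up and 1053 down in N-replete and 3193 up and 1222 down in N-deprived medium, and after median-ratio centring 251 up and 1584 down and 444 up and 1946 down. From 24 to 48 h the N-replete cells changed by 200 genes up and 149 down and the N-deprived cells by 32 up and 70 down, and after median-ratio centring by 153 up and 198 down and by 28 up and 82 down, so the larger direction in N-replete medium turned with the scaling; whether these steps differ between media was not tested as a count.

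Adjacent genes tended to change together. Neighbours on the same sequence included scaffold00009.g887 and scaffold00009.g888, 94 bp apart and both deeply lower at 3 h, and scaffold00214.g6292 and scaffold00214.g6293, 2004 bp apart and both higher at 48 h. At 3 h 23 adjacent pairs were both at least 2-fold lower where 5.3 are expected by chance, and at 48 h 183 pairs were both lower where 79.7 are expected and 167 both higher where 103.5 are expected.

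The joint change of adjacent genes was weighed against spill-over of fragments and against regional trends. Spearman's rho over 9289 adjacent pairs was 0.13 to 0.162 over the 6 times. Fragments counted for a neighbour are argued against as the whole cause, since rho for the 893 pairs more than 1000 bp apart was at least 0.107 at each time (permutation p 1.0e-05, the smallest 100000 permutations can give, to 0.0016; Benjamini-Hochberg adjusted over 6 tests at most 0.0016). A trend over whole regions is argued against by next-but-one genes, whose rho was at most 0.022. Shared promoters or tandem gene copies remain candidate explanations that were not tested, because strand and sequence were not used here.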
